A study of Mus musculus with 6 samples.

How the data were processed

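Messenger RNA from mouse liver was sequenced after 14 days of oral treatment, per the labels, with phosphate buffered saline (control, 3 libraries) or with a water extract of the plant Emilia sonchifolia (extract, 3 libraries). Libraries were made from total RNA after capture on oligo(dT) beads, per the labels' protocols, and whether they keep the strand is not given in the sources used here. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d and edgeR, with no role, setting or design for any of them. The genome build is not given in the sources used here. Of the 30889 gene identifiers in the deposited table, 30796 (99.7%) are in GENCODE release M21 on GRCm38. Of those, 90.7% have the same chromosome, start and end there, and 99.4% lie within the annotated gene, so coordinates are given on that build as the table prints them.

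The deposited table holds 2 kinds of value per library, per the file headers. The deposited estimated counts per gene are whole numbers and were used without rounding. Their low values peak at 4, which 6292 entries hold against 5334 at 1, 4205 at 2, 4117 at 3 and 2133 at 5, with 2400, 2316, 2414 and 1512 at 6, 7, 8 and 9. A peak at 4 is what 1 read pair adding about 4 counts would give, but how the counts were made is not given in the sources used here. The totals of 51219533 to 61432016 counts per library would then stand for about 4 times fewer read pairs, and a value of a few counts could come from a single pair. The second kind, FPKM as deposited by the authors, is scaled for gene length and for the number of mapped fragments. Another 6 columns of per-sample values match none of the samples and were not used. Each library was matched to its group by the group code and number shared by column name and sample title. The 2 groups differ in nothing else that the labels give, and no sequencing batch is named.

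Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with its default settings kept 18071 genes, TMM factors scaled the libraries, and the quasi-likelihood test compared extract with control, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change was taken from the fold change and the F statistic. The plan fixed before the data were examined named limma on log2(FPKM + 0.5) unless the table held counts, in which case edgeR was to take its place, and this applied. The 37 gene lists were also fixed beforehand. They were tested with camera (limma 3.58.1) at the preset correlation of 0.01 and again with an estimated correlation, two-sided, with adjustment over the lists. Lists share members, so their results are not independent of each other. FPKM values are given as mean ± SD of 3 libraries.

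Genes named in the report follow a rule fixed beforehand. Its first part takes the 10 largest rises and the 10 largest falls among genes past the threshold that are not predicted gene models, with a mean of at least 5 FPKM in a group and no overlap between groups. The second takes up to 4 members of each list with the smallest p, from which examples are given, and the third a fixed set of 15 liver genes. Pseudogenes and members of gene families with near-identical copies can exchange reads in the counting, and their values are uncertain. The same holds for overlapping and antisense genes, since no use of strand is stated.

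The steps were tested on counts simulated for the 18071 genes of the comparison of extract with control, of which 200 were changed. edgeR recovered 59% of changes of 1 on the log2 scale and 74% of changes of 2, and 13 of its 146 calls (8.90%) were false, above the nominal 5%. DESeq2 recovered 69% and 77%, with 49 of 195 calls false (25.1%). limma on log2(CPM + 0.5) recovered 59% and 75%, with 17 of 151 calls false (11.3%). This was a single simulation with 200 changed genes, where edgeR called 4870 genes in the data. Its shares therefore need not hold for the real calls. The limma fit simulated here used CPM, not the FPKM used for the data. The alternatives were limma on FPKM with other pseudocounts, filters, scalings and a robust fit, DESeq2 1.42.0, edgeR without the filter on low counts or with the replicate number as a block, each library left out in turn, and a bound on the fold change. Pathway terms printed in the table were tested with one-sided Fisher's exact tests. No library was left out of the main comparison.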

Results

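The data are 6 liver RNA libraries from mice treated by mouth for 14 days, 3 from animals given phosphate buffered saline (control) and 3 from animals given a water extract of Emilia sonchifolia (extract), a herb of the daisy family. The control libraries held 51219533, 61432016 and 52021514 estimated counts and the extract libraries 52941399, 56603387 and 54748033. Between 22649 and 24178 genes were above 0 in each library. Pearson correlations of log2 FPKM across genes ran from 0.955 to 0.965 between groups, from 0.971 to 0.984 within control and from 0.987 to 0.990 within extract. The first principal component held 41.7% of the variance and parted the groups, and the second held 24.5% and parted control 1 from control 3. The labels do not say that each library is a separate animal, so the p-values measure the spread between these libraries, which may be technical.

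The comparison asks which liver transcripts differ between mice given the extract and mice given saline. Transcripts of cholesterol synthesis, bile acid synthesis, lipogenesis, interferon response and conjugation of foreign compounds were higher with the extract at the preset correlation of camera, and not called at an estimated one. Those of red cells, leukocytes and Kupffer cells, the resident macrophages of the liver, were lower. None of these was called at an estimated correlation either, where camera called 0 of the 37 lists, 11 at an unadjusted p under 0.05. Cyp7a1, the rate-limiting enzyme of the classic bile acid pathway, went from 10.5 ± 2.01 to 104 ± 3.30 FPKM (SD, n = 3), and Plin4, a lipid droplet protein, from 8.78 ± 0.160 to 0.710 ± 0.0232 FPKM. edgeR called 4870 of the 18071 genes tested, 2561 higher and 2309 lower with the extract. Of these, 954 differed by at least 1 on the log2 scale, 353 higher and 601 lower. The values of the groups did not overlap for 8064 genes (44.6%), where chance gives 10%. The number of calls was 3237 without extract 2, and the lower calls numbered 1442 without control 2, 1480 without extract 1 and 1461 without extract 2. On FPKM as deposited, limma called 4206 of 10817 genes, of which 41.3% were higher, against 52.6% in the main test. With TMM factors on the FPKM it was 50.1%.

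**Figure D1:**
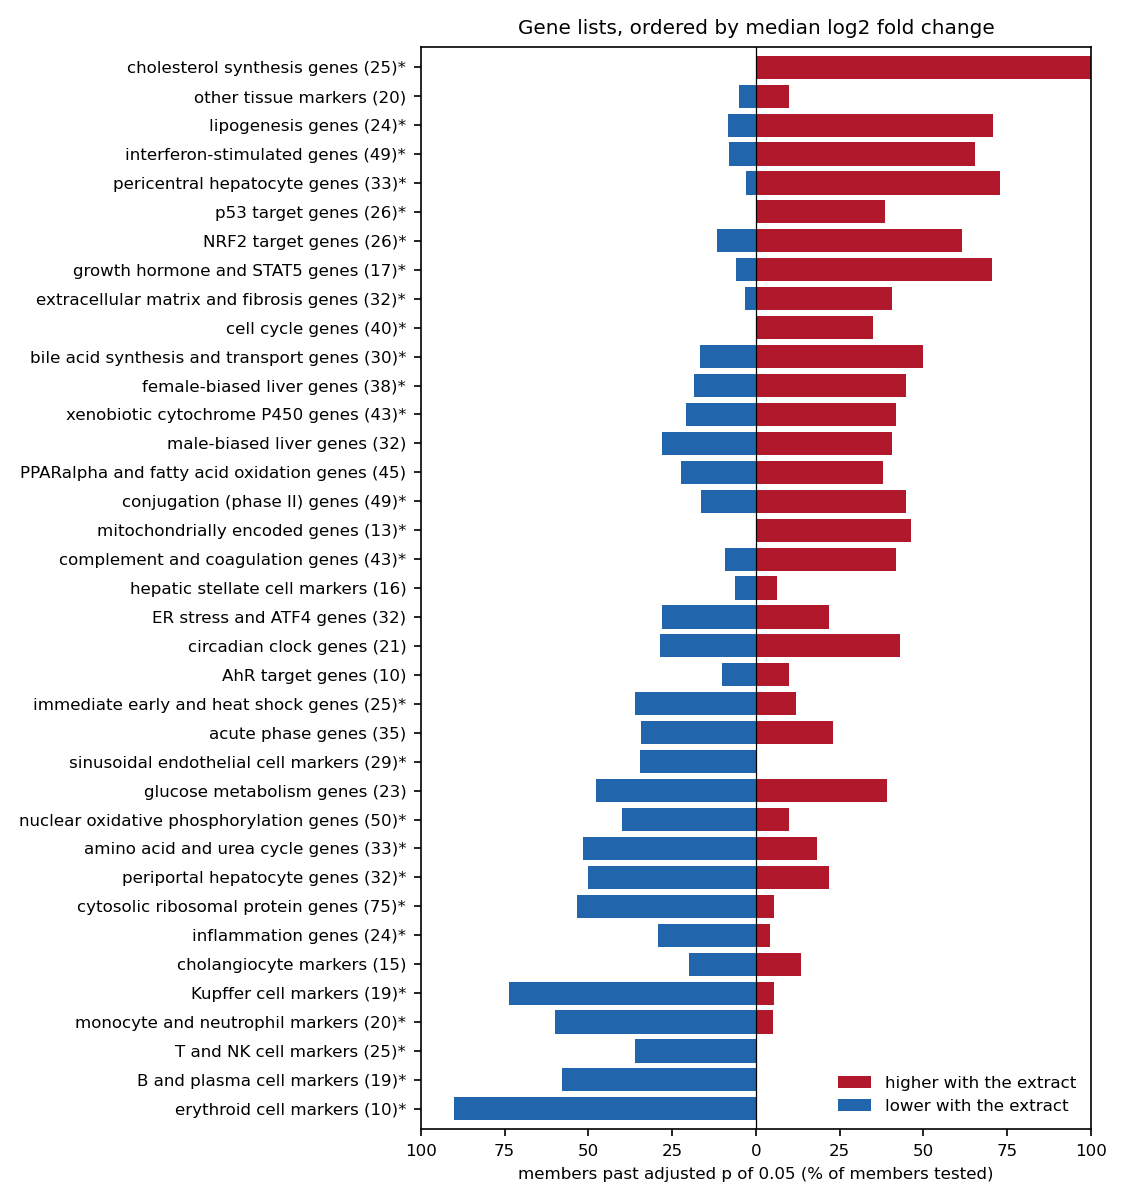
Share of the members of each of 37 gene lists that were higher (red, to the right) or lower (blue, to the left) with the extract at an edgeR adjusted p of 0.05, in percent of the members tested, whose number stands in parentheses; an asterisk marks lists with a camera adjusted p under 0.05. All 25 cholesterol synthesis genes were higher, and 9 of 10 erythroid cell markers were lower.

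All 25 genes of the cholesterol synthesis list rose, over all genes tested and adjusted over the list alone, with a median log2 fold change of 1.26 (camera adjusted p = 1.66e-61, and adjusted p = 0.0868 with an estimated correlation). Hmgcs1, a synthase early in the pathway (ENSMUSG00000093930, GRCm38 chromosome 13, gene span 119690379 to 119708260), went from 26.4 ± 2.94 to 85.1 ± 3.85 FPKM. Its log2 fold change was 1.75 ± 0.08 (SE, edgeR adjusted p = 9.21e-06), and it was higher in all 3 extract libraries than in any control library. Hsd17b7 and Fdft1, enzymes of the same pathway, rose 2.90-fold and 2.27-fold. In the bile acid list, 15 of 30 genes rose and 5 fell (17 and 5 adjusted over the list alone), with a median of 0.23 (camera adjusted p = 0.000150, and adjusted p = 0.215 with an estimated correlation). Cyp7a1 (ENSMUSG00000028240, GRCm38 chromosome 4, gene span 6265612 to 6275633) had the largest rise of that list, with a log2 fold change of 3.37 ± 0.13 (SE, edgeR adjusted p = 4.18e-06). Baat, which conjugates bile acids to amino acids, rose 1.51-fold. Nr0b2, a repressor of Cyp7a1, fell by 0.94 on the log2 scale, and the transporter Slco1a4 fell by 0.82.

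Of 24 lipogenesis genes, 17 rose and 2 fell (18 and 2 adjusted over the list alone), with a median of 0.58 (camera adjusted p = 3.29e-13, and adjusted p = 0.216 with an estimated correlation). Srebf1, the transcription factor that drives fatty acid synthesis, went from 25.1 ± 0.910 to 59.1 ± 3.28 FPKM. The elongase Elovl6 rose 3.10-fold and Gpam, the first enzyme of glycerolipid synthesis, 1.98-fold, while the phosphatase Lpin1 fell by 0.80 on the log2 scale. The list of PPARalpha targets and fatty acid oxidation genes was not called (17 of 45 higher and 10 lower, 20 and 12 adjusted over the list alone, camera adjusted p = 0.248, adjusted p = 0.701 with an estimated correlation). With no filter on low counts its adjusted p was 0.0313. Its members moved both ways. Vnn1 rose 3.42-fold, and the lipid droplet protein Plin5 and the lipase inhibitor Angptl4 fell by 1.68 and 1.42 on the log2 scale. Plin4 (ENSMUSG00000002831, GRCm38 chromosome 17, gene span 56100591 to 56109803) fell by 3.56 ± 0.06 on the log2 scale (SE, edgeR adjusted p = 1.83e-07). In the glucose metabolism list, 9 of 23 genes rose and 11 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.140, and adjusted p = 0.558 with an estimated correlation). Irs2, an insulin receptor substrate, rose 4.03-fold and Pfkfb3 fell by 1.25 on the log2 scale.

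Among 26 NRF2 target genes, 16 rose and 3 fell, over all genes and adjusted over the list alone, with a median of 0.40 (camera adjusted p = 5.62e-11, and adjusted p = 0.0515 with an estimated correlation). Osgin1 rose 2.77-fold, the epoxide hydrolase Ephx1 2.30-fold and the quinone reductase Nqo1 1.94-fold, while Hmox1, the inducible heme oxygenase, fell by 0.66 on the log2 scale. Of 49 genes of phase II conjugation, 22 rose and 8 fell (22 and 9 adjusted over the list alone), with a median of 0.13 (camera adjusted p = 9.07e-08, and adjusted p = 0.177 with an estimated correlation). The glutathione transferases Gstp1, Gsta3 and Gstm1 rose 1.96-fold, 1.89-fold and 1.84-fold, and the related Gsta2 rose from 1.35 ± 0.349 to 6.65 ± 0.171 FPKM, all of them members of families whose copies can share reads. In the cytochrome P450 list, 18 of 43 genes rose and 9 fell (20 and 11 adjusted over the list alone), with a median of 0.20 (camera adjusted p = 0.00652, and adjusted p = 0.455 with an estimated correlation). That call was lost without control 3, at an adjusted p of 0.0664. It was also lost with limma on FPKM (0.0658), with TMM factors on FPKM (0.0894), with quantile normalization (0.146) and on genes of at least 5 FPKM (0.114). Por, the electron donor of these enzymes, rose 1.42-fold and Cyp2d26 fell by 0.44 on the log2 scale. Of the fixed P450 genes, Cyp2b10 rose 1.61-fold and Cyp2e1 1.26-fold, the latter not called with limma on FPKM without a filter on low values (adjusted p = 0.0743). Cyp3a11 was at 731 ± 33.4 and 662 ± 14.3 FPKM (edgeR adjusted p = 0.220, limma on FPKM 0.0420) and Cyp1a2 at 171 ± 30.0 and 192 ± 7.55 (edgeR adjusted p = 0.170, 0.0196 without control 1). Of 10 AhR targets, 1 rose, Nqo1, and 1 fell, Tiparp, the same numbers adjusted over the list alone (camera adjusted p = 0.788, adjusted p = 0.794 with an estimated correlation). The median and mean of that list were below 0 and the camera direction was up.

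Genes that follow growth hormone and STAT5 were higher, 12 of 17 rising and 1 falling (12 and 2 adjusted over the list alone), with a median of 0.39 (camera adjusted p = 9.59e-09, and adjusted p = 0.105 with an estimated correlation). The STAT5 targets Cish and Socs2 rose 4.59-fold and 2.54-fold, and Bcl6, which STAT5 represses, was the 1 member that fell, by 1.45 on the log2 scale. Of 38 genes known to be higher in female liver, 17 rose and 7 fell (18 and 8 adjusted over the list alone), with a median of 0.21 (camera adjusted p = 0.000827, and adjusted p = 0.180 with an estimated correlation). The call was lost with TMM factors on FPKM (limma adjusted p = 0.0568) and with quantile normalization (limma adjusted p = 0.0813). Sult3a2, a sulfotransferase (ENSMUSG00000090298, GRCm38 chromosome 10, gene span 33766424 to 33786704), went from 0.521 ± 0.0869 to 14.4 ± 4.41 FPKM, and the transporter Slc22a27 rose 4.28-fold. The list of male-biased genes was not called (13 of 32 higher and 9 lower, 13 and 10 adjusted over the list alone, camera adjusted p = 0.485, adjusted p = 0.717 with an estimated correlation), and its median of 0.14 and mean of -0.19 differed in sign. Hsd3b5 and Mup21, a urinary protein from a family of near-identical genes, fell by 2.20 and 2.17 on the log2 scale, while Nudt7 and Gstp1 rose 2.02-fold and 1.96-fold.

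Of 33 pericentral hepatocyte genes, those highest around the central vein, 24 rose and 1 fell (26 and 1 adjusted over the list alone), with a median of 0.53 (camera adjusted p = 1.31e-18, and adjusted p = 0.105 with an estimated correlation). Glul, glutamine synthetase, rose from 153 ± 3.79 to 215 ± 2.20 FPKM, Gstm3 rose 3.63-fold and Ahr 2.02-fold. Of 32 periportal genes, 7 rose and 16 fell (9 and 18 adjusted over the list alone), with a median of -0.16 (camera adjusted p = 0.00157, and adjusted p = 0.287 with an estimated correlation). Sds, serine dehydratase, fell by 1.53 on the log2 scale, Etnppl by 0.70 and Pck1, a key enzyme of gluconeogenesis, by 0.52. In the list of amino acid and urea cycle genes, 6 of 33 rose and 17 fell (7 and 18 adjusted over the list alone), with a median of -0.16 (camera adjusted p = 0.000801, and adjusted p = 0.391 with an estimated correlation). The aminotransferases Tat and Agxt fell by 0.76 and 0.65 on the log2 scale, and Prodh rose 1.45-fold.

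Interferon-stimulated genes were higher, with 32 of 49 rising and 4 falling (33 and 4 adjusted over the list alone) and a median of 0.56 (camera adjusted p = 2.56e-19, and adjusted p = 0.166 with an estimated correlation). Ifi44 rose 2.81-fold, the nucleic acid sensors Zbp1 and Ifih1 2.43-fold and 2.26-fold, and the GTPase Irgm2 1.63-fold. Of 24 inflammation genes, 1 rose, Il1b by 2.13-fold, and 7 fell (2 and 8 adjusted over the list alone), with a median of -0.28 (camera adjusted p = 0.00992, and adjusted p = 0.147 with an estimated correlation). The adhesion molecule Vcam1 fell by 1.47 on the log2 scale and the NF-kappa B inhibitor Nfkbia by 0.70. The acute phase list was not called (8 of 35 higher and 12 lower, 8 and 13 adjusted over the list alone, camera adjusted p = 0.135, adjusted p = 0.789 with an estimated correlation), but was lower without control 1 (adjusted p = 0.00310) or control 2 (adjusted p = 0.0311). Serpina3m and Steap4 rose 1.57-fold and 1.40-fold. The gene span of Serpina3m contains that of a family member that rose 1.72-fold and can share its reads, so the Serpina3m value is uncertain. The metallothioneins Mt1 and Mt2 fell by 1.04 and 1.02 on the log2 scale, and Saa1, whose near-identical copy can take its reads, went from 1601 ± 526 to 770 ± 72.6 FPKM (edgeR adjusted p = 0.00856). Of 43 complement and coagulation genes, 18 rose and 4 fell (18 and 6 adjusted over the list alone), with a median of 0.07 (camera adjusted p = 0.00156, and adjusted p = 0.441 with an estimated correlation). The complement call was lost with limma on FPKM (0.0574), with quantile normalization (0.0840) and on genes of at least 5 FPKM (0.114). F5, a clotting factor, rose 1.39-fold and C4bp, a regulator of complement, 1.34-fold.

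Markers of red cells and of immune cells were lower with the extract. The share of counts from 4 globin genes was 0.125% ± 0.0158 in control and 0.0181% ± 0.00221 in extract (SD, n = 3). Of 10 erythroid markers, 9 fell (10 adjusted over the list alone), with a median of -2.67 (camera adjusted p = 3.91e-31, and adjusted p = 0.0868 with an estimated correlation). Hbb-bs, a beta globin gene (ENSMUSG00000052305, GRCm38 chromosome 7, gene span 103826534 to 103827928), went from 445 ± 46.3 to 68.0 ± 4.38 FPKM, and the other globin genes named by the rule, Hbb-bt, Hba-a1 and Hba-a2, fell by 2.64, 2.92 and 2.69 on the log2 scale, with reads that near-identical copies can share. Of 20 monocyte and neutrophil markers, 12 fell and 1 rose (13 and 2 adjusted over the list alone), with a median of -0.85 (camera adjusted p = 1.44e-07, and adjusted p = 0.0950 with an estimated correlation). Camp and Ngp, proteins of neutrophil granules, fell by 5.19 and 4.55 on the log2 scale, to 0.201 ± 0.227 and 0.703 ± 0.231 FPKM, and S100a9 went from 42.4 ± 14.7 to 6.24 ± 0.830 FPKM. Of 19 B and plasma cell markers, 11 fell and 0 rose (13 and 0 adjusted over the list alone), with a median of -1.21 (camera adjusted p = 1.02e-05, and adjusted p = 0.301 with an estimated correlation), and of 25 T and NK cell markers 9 fell and 0 rose (13 and 0 adjusted over the list alone), with a median of -0.92 (camera adjusted p = 0.000254, and adjusted p = 0.0868 with an estimated correlation). Igkc, an antibody light chain, fell by 1.46 on the log2 scale and Il2rb, an interleukin receptor of T and NK cells, by 1.28.

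Of 19 Kupffer cell markers, 14 fell and 1 rose (15 and 1 adjusted over the list alone), with a median of -0.56 (camera adjusted p = 3.96e-10, and adjusted p = 0.0515 with an estimated correlation). Csf1r, the receptor for macrophage growth factor, went from 14.6 ± 0.349 to 7.49 ± 0.345 FPKM, and Fcna, Vsig4 and C1qa fell by 0.89, 0.85 and 0.79 on the log2 scale. Of 29 sinusoidal endothelial markers, 10 fell and 0 rose, the same numbers adjusted over the list alone, with a median of -0.12 (camera adjusted p = 0.00715, and adjusted p = 0.391 with an estimated correlation). Stab1 and Mrc1, scavenger receptors, fell by 0.78 and 0.76 on the log2 scale. The stellate cell list was not called, with 1 of 16 markers higher and 1 lower, 0 adjusted over the list alone, and a median of 0.01 (camera adjusted p = 0.9998, and adjusted p = 0.9999 with an estimated correlation). The cholangiocyte list was not called either (2 of 15 higher and 3 lower, the same numbers adjusted over the list alone, camera adjusted p = 0.651, adjusted p = 0.701 with an estimated correlation). Sox9, a transcription factor of bile duct cells, fell by 1.26 on the log2 scale and Slc4a2, an anion exchanger, rose 1.26-fold. In the list of extracellular matrix and fibrosis genes, 13 of 32 rose and 1 fell (14 and 2 adjusted over the list alone), with a median of 0.34 (camera adjusted p = 0.0293, and adjusted p = 0.499 with an estimated correlation). This call was lost without control 1, control 3 or extract 1 (adjusted p = 0.0815, 0.0910 and 0.140) and with DESeq2 (0.0520), counts divided by 4 (0.101) or limma on FPKM (0.146). TMM factors on FPKM (0.236), quantile normalization (0.253) and a mean of at least 5 FPKM (0.386) also ended it. Lum rose 2.48-fold and Ccn2, a matrix signalling protein, fell by 0.84 on the log2 scale.

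**Figure D2:**
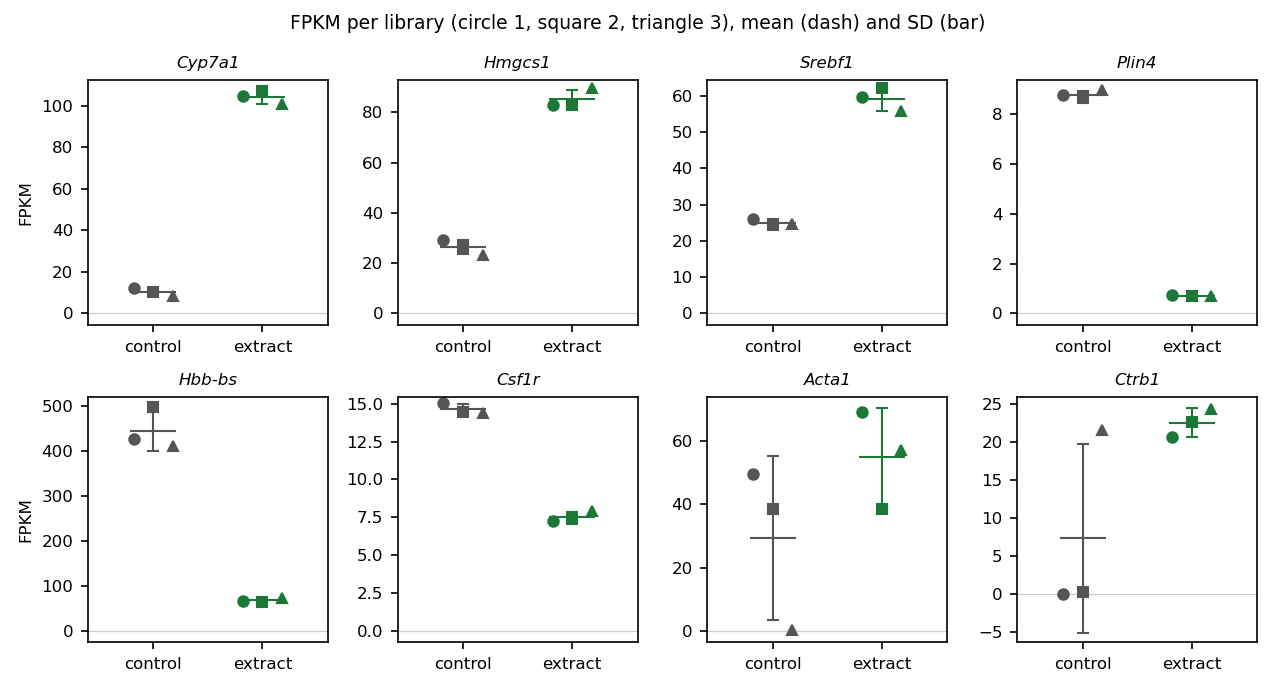
FPKM of 8 genes in each library (vertical axes, grey line at 0), with control in grey and extract in green, the mean as a dash and the SD as a bar. Cyp7a1, Hmgcs1 and Srebf1 were higher and Plin4, Hbb-bs and Csf1r lower in all 3 extract libraries, while Acta1 was near 0 in control 3 alone and Ctrb1 near 0 in controls 1 and 2 alone.

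Of 20 markers of other tissues, 2 rose, 1 fell and 17 did not pass (1 and 1 adjusted over the list alone, camera adjusted p = 0.188, adjusted p = 0.391 with an estimated correlation). The median of 1.15 came with an uneven spread over the libraries, and without control 3 the list was higher at an adjusted p of 3.73e-14. It was also called higher with the replicate block (camera adjusted p = 0.0254) and with limma on FPKM without a filter on low values (camera adjusted p = 0.0209). The pancreas gene Ctrb1 was at 0.00, 0.245 and 21.6 FPKM in controls 1, 2 and 3 and at 20.6, 22.7 and 24.3 FPKM in the extract libraries, and it was called without control 3 alone (edgeR adjusted p = 0.000114). The muscle gene Acta1 was at 49.7, 38.4 and 0.216 FPKM in the controls and at 69.1, 38.6 and 57.2 FPKM in the extract libraries.

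Transcripts of p53 targets were higher, 10 of 26 rising and 0 falling (12 and 0 adjusted over the list alone), with a median of 0.46 (camera adjusted p = 0.000479, and adjusted p = 0.0868 with an estimated correlation). With limma on genes of at least 5 FPKM the adjusted p was 0.114. Plk2 and Ccng1 rose 2.29-fold and 1.65-fold and Mdm2, the p53 ubiquitin ligase, 1.39-fold, while Cdkn1a was at 2.90 ± 0.643 and 3.11 ± 0.222 FPKM (edgeR adjusted p = 0.466, 0.0386 without control 3). Of 40 cell cycle genes, 14 rose and 0 fell (16 and 0 adjusted over the list alone), with a median of 0.31 (camera adjusted p = 0.000491, and adjusted p = 0.287 with an estimated correlation). Mcm6 and Mcm4, parts of the replicative helicase, rose 4.93-fold and 2.42-fold from below 1 FPKM, and Ccnd1 rose 1.89-fold. Of 25 immediate early and heat shock genes, 3 rose and 9 fell (4 and 9 adjusted over the list alone), with a median of -0.07 (camera adjusted p = 0.0238, and adjusted p = 0.309 with an estimated correlation). The immediate early call was lost without control 3 (adjusted p = 0.0659) or with limma on FPKM (adjusted p = 0.0686), also with TMM factors (0.0601) or quantile normalization (0.0575). The phosphatase Dusp1 fell by 1.21 on the log2 scale and Zfp36 by 0.53. The ER stress and ATF4 list was not called (7 of 32 higher and 9 lower, the same numbers adjusted over the list alone, camera adjusted p = 0.834, adjusted p = 0.827 with an estimated correlation). Its median of -0.02 and mean of 0.05 differed in sign. Herpud1 fell by 0.67 on the log2 scale, the chaperone Calr by 0.51, and Xbp1 rose 1.27-fold.

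Of 75 cytosolic ribosomal protein genes, 40 fell and 4 rose (44 and 5 adjusted over the list alone), with a median of -0.23 (camera adjusted p = 5.70e-07, and adjusted p = 0.441 with an estimated correlation). Rps2 fell by 1.68 on the log2 scale and Rpl34 rose from 2.59 ± 0.297 to 6.36 ± 0.222 FPKM, but these genes share reads with many pseudogenes and single values are uncertain. Of 50 nuclear genes of oxidative phosphorylation, 20 fell and 5 rose (24 and 5 adjusted over the list alone), with a median of -0.15 (camera adjusted p = 0.00863, and adjusted p = 0.338 with an estimated correlation). Ndufa2 and Ndufb7, subunits of complex I, fell by 0.42 and 0.37 on the log2 scale. Of 13 mitochondrially encoded genes, 6 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 0.10 (camera adjusted p = 0.000479, and adjusted p = 0.287 with an estimated correlation), mt-Nd5 by 1.66-fold and mt-Nd4l by 1.53-fold. Mitochondrially encoded genes held 3.67% ± 0.0779 of counts in control and 3.95% ± 0.0756 in extract (SD, n = 3). The circadian clock list was not called (9 of 21 higher and 6 lower, 10 and 8 adjusted over the list alone, camera adjusted p = 0.744, adjusted p = 0.794 with an estimated correlation). Ciart and Noct fell by 1.47 and 0.80 on the log2 scale, and Wee1 rose 2.37-fold.

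**Figure D3:**
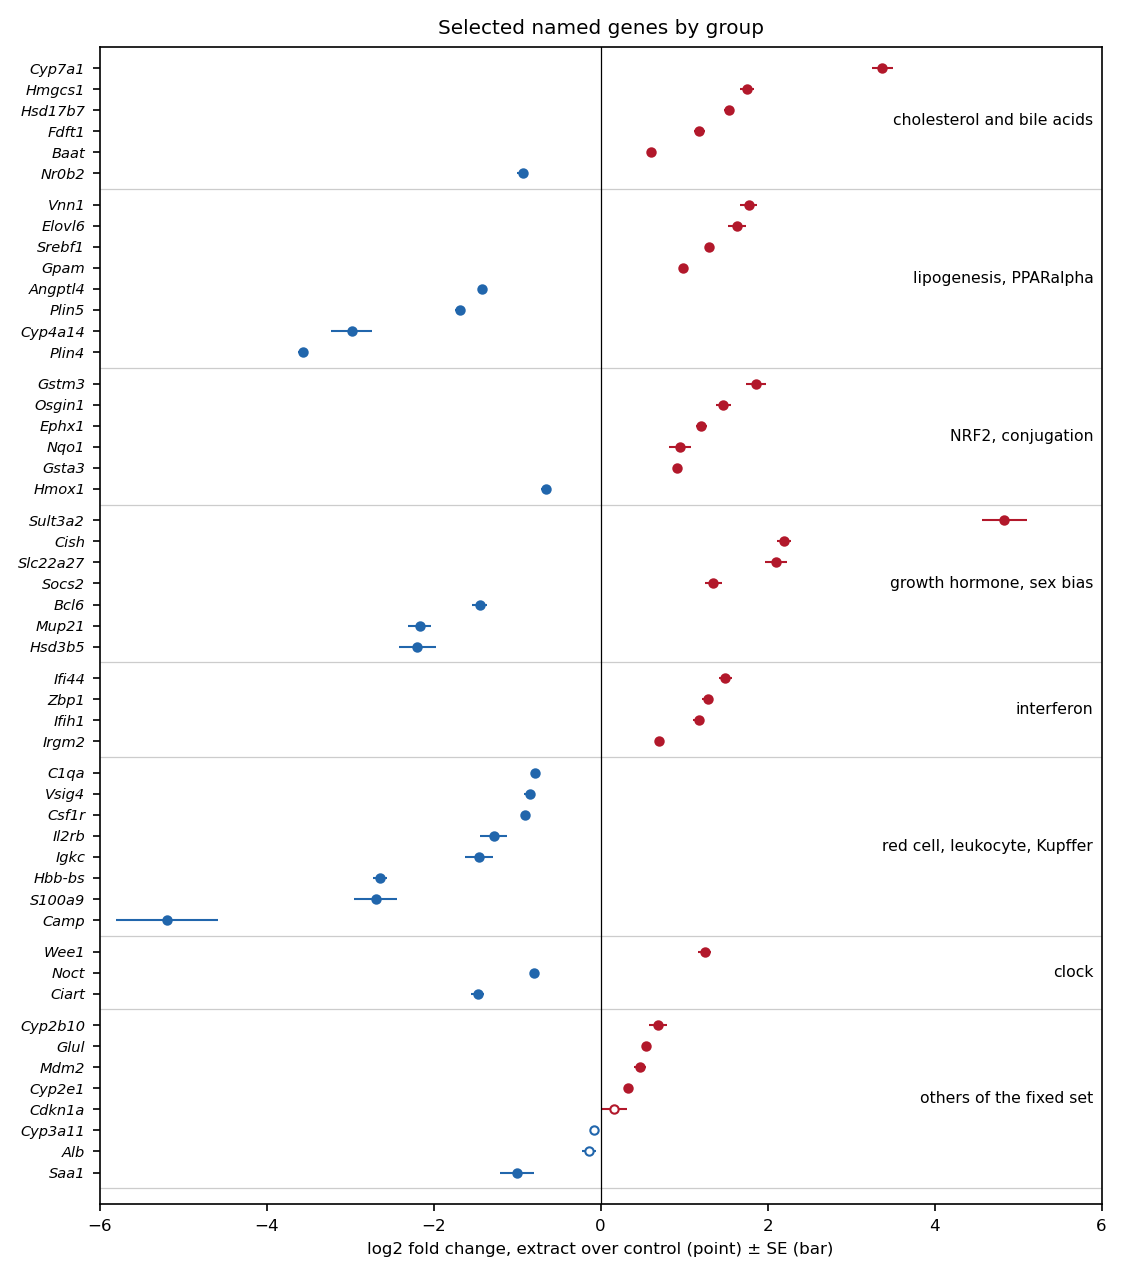
Log2 fold change of a selection of the named genes, without pseudogenes, extract over control, from edgeR (points) with its standard error (bars), in 8 groups; red points were higher and blue points lower with the extract, and open points had an adjusted p of 0.05 or more. Among the genes drawn, Sult3a2 at 4.83 and Cyp7a1 at 3.37 stand farthest to the right, and Camp at -5.19 and Plin4 at -3.56 farthest to the left, while Ngp at -4.55 is not drawn.

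The 10 largest rises by the naming rule were, on the log2 scale, Sult3a2 with 4.83, Got2-ps1 with 3.44, Cyp7a1 with 3.37, the transcription factor Onecut1 with 3.03, Rps24-ps3 with 2.83, the guanylate binding protein Gbp11 with 2.73, Nrep with 2.57, Gsta2 with 2.35, Sult3a1 with 2.32 and Hamp2, a hepcidin, with 2.28. The 10 largest falls were Camp with -5.19, Ngp with -4.55, Rps26-ps1 with -4.10, Plin4 with -3.56, the antigen-presenting H2-Ea with -3.07, the fatty acid hydroxylase Cyp4a14 with -2.98, Hba-a1 with -2.92, Ap3s1-ps2 with -2.89, Mup12 with -2.77 and S100a9 with -2.70. edgeR adjusted p-values of these 20 genes ran from 1.83e-07 to 0.00443. Got2-ps1, Rps24-ps3, Rps26-ps1 and Ap3s1-ps2 are pseudogenes, and the Sult3a, Gsta, Hamp, Mup and globin genes have near-identical copies, so their values are uncertain. Of the fixed set, Fgf21 was at 1.41 ± 0.395 and 1.92 ± 0.685 FPKM (edgeR adjusted p = 0.285). The desaturase gene Scd1 was at 302 ± 94.5 and 430 ± 9.91 FPKM (edgeR adjusted p = 0.0639, 0.0113 without control 1 and 0.0199 without control 3), and with counts divided by 4 its adjusted p was 0.0490. Albumin (Alb) was at 29910 ± 4101 and 26017 ± 163 FPKM (edgeR adjusted p = 0.275, 0.00702 without control 3).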

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

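The counts divided by 4 and edgeR with DESeq2 size factors were chosen after seeing the data, and the other alternatives before the data were examined. No gene called in both the main test and an alternative changed direction, and 2743 of the 4870 calls were kept in each of the 6 fits without a library. DESeq2 shared 4757 and limma on FPKM 3392 of these calls. The calls past a log2 fold change of 1 numbered 954, with 353 higher and 601 lower. limma without a filter on low values gave 1485 higher calls, of 3746 calls over 29485 genes (the cause was not tested), and limma on genes of at least 5 FPKM gave 2460 calls, 1089 higher and 1371 lower, because it tested only 4882 genes. Leaving out each library gave 3237 (without extract 2) to 4706 calls, 1776 to 2553 of them higher, 1442 (without control 2) to 2153 lower, and 25 to 28 lists, against 27 in the main test. Fewer samples left fewer gene calls in each of these 6 fits.

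With an estimated correlation camera called 0 of the 37 lists, 11 at an unadjusted p under 0.05. This setting changes the correlation between genes and also leaves the test fewer degrees of freedom. Which of these ended the calls was not tested. Under the other alternatives 24 lists kept direction and call wherever they were tested, another 4 were called in no alternative but reversed in camera's direction, and the calls of 9 changed. The cause was not tested for these. For the 9, the adjusted p ran, over 19 alternatives, from 1.17e-06 to 0.114 for p53 targets, 3.43e-05 to 0.0813 for female-biased genes, 1.01e-05 to 0.114 for complement, 0.000425 to 0.146 for P450 genes, 0.00997 to 0.0686 for immediate early genes, 0.00158 to 0.386 for extracellular matrix, 0.00310 to 0.872 for acute phase, 3.73e-14 to 0.906 for other tissues and 0.0313 to 0.519 for PPARalpha targets. The circadian clock list reversed with limma on FPKM at pseudocounts of 0.5, 1 and 0.1 (adjusted p = 0.5646, 0.5649 and 0.5637), robust (0.5646), without a filter (0.718), with TMM factors (0.687) and with quantile normalization (0.795). In these settings, in the same order, the stellate cell list reversed at 0.8998, 0.896, 0.906, 0.8998, 0.972, 0.858 and 0.825. It also reversed at 5 FPKM or more (0.336), with DESeq2 (0.877) and with counts divided by 4 (0.889). Without 1 library, stellate cells reversed without control 3, extract 1 or extract 3 (adjusted p over the 6 fits 0.437 to 0.9995), male-biased genes without extract 3 (0.205 to 0.896) and ER stress genes without extract 2 (0.697 to 0.9969). Of the 141 genes named, 131 kept direction and call wherever tested. The exceptions were Alb (adjusted p from 0.00702 to 1), Cdkn1a (0.0386 to 0.864), Ctrb1 (0.000114 to 0.626), Cyp1a2 (0.0196 to 0.485), Cyp2e1 (4.09e-12 to 0.0743), Cyp3a11 (0.0336 to 0.578), Scd1 (0.0113 to 0.217), Prtn3 (0.0189 to 0.174), and Klf1 and Reg3b, neither called, whose log2 fold changes without 1 library ran from -0.1695 to 0.0109 (reversed without extract 3) and from -1.70 (reversed without extract 1) to 3.725. If 1 read pair adds about 4 counts, a value of a few counts can be 1 pair, which limits genes of low level: with counts divided by 4, 5109 genes were called, and 4695 of the 4870 were among them.

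With the replicate number as a replicate block, edgeR called 3746 genes and camera 28 lists, among them other tissues (adjusted p = 0.0254), and Scd1 had an adjusted p of 0.0466. Deviations from the group mean had correlations of -0.117, -0.028 and -0.089 across genes between libraries of the same number. Between libraries of different numbers the correlations ran from -0.069 to 0.153. The numbers thus gave no sign of pairing, but 3 libraries per group cannot exclude it.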

Other observations

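The sum over 14 genes of immature blood cells, the camera tests of the fixed lists and the genes of the naming rule were set beforehand. The other tests and the other genes singled out in this part were chosen after the results were seen.

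The deposited table gives pathway terms for its genes, and 304 terms of 10 to 300 tested genes were examined in both directions, which makes 608 one-sided Fisher's exact tests with adjustment over all of them. The background was the 6045 tested genes that carry a term. Of the terms, 28 were called for genes higher with the extract and 27 for genes lower. Fisher's test treats genes as independent, which they are not. The porphyrin term had 20 of 39 genes higher (odds ratio 4.64, adjusted p = 0.000326), while the globins were lower. Among the genes of heme synthesis, Cpox rose by 0.74, Alas1 by 0.46, Alad by 0.39 and Fech by 0.34 on the log2 scale, each higher in all 3 extract libraries than in any control library. No list of heme synthesis genes was tested. The peroxisome term had 35 of 82 genes higher (odds ratio 3.31, adjusted p = 4.27e-05), among them Acsl4 with a 2.47-fold and Idh1 with a 1.48-fold rise. The antigen processing term had 23 of 70 genes lower (odds ratio 2.65, adjusted p = 0.00687). In it the class II genes H2-Aa, H2-Eb1 and H2-Ab1 fell by 1.46, 1.34 and 1.12, and Cd74, their invariant chain, fell by 1.15. Lists that hold markers of cells that carry class II, among other cells, were lower as well. Their medians were -1.21 for B and plasma cells, -0.85 for monocytes and neutrophils and -0.56 for Kupffer cells. The T and NK cell list was also lower, with a median of -0.92, and none of these lists was called at the estimated correlation. The terms for PPAR signaling (27 of 72 genes, adjusted p = 0.00422) and fatty acid degradation (18 of 46, adjusted p = 0.0153) were called higher, where the fixed list of PPARalpha targets and fatty acid oxidation genes was not called. In the PPAR term, another 18 genes were lower.

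The liver transcription factors Foxa2 and Hhex rose 2.49-fold and 2.20-fold, beside the rise of Onecut1 to 9.05 ± 2.59 from 1.15 ± 0.373 FPKM (SD, n = 3). Ddit4, Tsc22d3, Sgk1, Per1 and Fkbp5, picked as genes that glucocorticoids can induce, had log2 fold changes of -1.91, -1.36, -0.77, -0.50 and -0.29 (edgeR adjusted p from 3.26e-06 for Tsc22d3 to 0.00429 for Fkbp5). Each of these 5 was lower in all 3 extract libraries than in any control library, but no list of such genes was tested.

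Red cell, leukocyte and Kupffer cell lists were lower with the extract at the preset correlation, and none of them was called at the estimated one (adjusted p from 0.0515 to 0.301). A lower share of all non-hepatocyte cells as the whole cause is argued against by medians only, since that of stellate cells lay 0.57 above that of Kupffer cells. The permutation p over genes (two-sided, 0.00018) treats the genes of a list as independent, which they are not, and does not measure the spread between libraries. Medians of cholangiocyte markers, not called, and sinusoidal endothelial markers were also below 0, at -0.35 and -0.12. Less blood leaves resident cells unchanged, so by itself it does not account for the Kupffer cell median of -0.56. That median was known beforehand and is part of the pattern, so it is no separate test. For red cells and leukocytes less blood in the tissue stays open, since the highest median of the 4 lists, -0.85, restates the pattern and decides nothing, as does an effect of the extract on these cells. Fewer immature blood-forming cells cannot be told apart from less blood: the planned sum over 14 genes, in counts scaled by library total, fell by 0.86 on the log2 scale, less than the globins' median of -2.67 and so against it by the bound set beforehand, but Prtn3, whose counts ran from 2144 to 3200 in all 6 libraries, made up 90.7% to 92.7% of the extract sums, so that the sum mostly measured that gene. Without Prtn3 and Klf1, left out after their values were seen and so no evidence for that explanation, the log2 ratio was -4.97, and Mpo went from 953, 1053 and 364 counts in the controls to 29, 9 and 24 in the extract libraries.

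Cyp7a1 and the cholesterol synthesis list were higher, the list not called at the estimated correlation (adjusted p = 0.0868), and clock genes moved both ways. For the cholesterol synthesis genes, the lowest median log2 fold change over 4 other scalings of the libraries was 1.11. These scalings differed little, with medians of all genes tested from -0.0373 to 0.00531, so they could not have removed the rise. They show only that the choice among them does not account for it. Livers of the extract group taken later in the day may explain the clock genes, since 6 night-peaking genes lay 1.03 above 4 earlier-peaking ones at the median. But the exact permutation p over genes, which are not independent, was 0.0762 (two-sided). Noct fell against this, as did another night-peaking gene (-0.22), and an earlier-peaking gene rose (0.15), neither of these others called. No hour is given in the sources used here, so a later hour cannot be told apart from an effect of the extract. Less bile acid signalling through FXR, a nuclear receptor that lowers Cyp7a1, could explain the rise of Cyp7a1 and stays open, because its 8 targets had a median of -0.0594 with a scaled median absolute deviation of 0.338, with 4 above and 4 below 0. Among these targets, Nr0b2 (-0.94) and others at -0.41 and -0.26 were called lower. Another at 0.20 was called higher, and the rest were not called.

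Muscle and pancreas transcripts were near 0 in some controls and present in the other libraries. Reads passing between these 6 libraries are argued against, since the highest library was 1.03 times the next at the median of 5 pancreas genes. A single pool of RNA behind the 3 extract libraries stays open. Muscle genes speak against it, since their highest to lowest ratio of 1.61 among these libraries lay at percentile 97.3 of genes of like level. But they vary together and were picked after their values were seen, so they do not settle it. Over genes with a mean of at least 10 FPKM, the SD was at the median 3.64% of the mean within extract and 5.16% within control. A piece of other tissue carried over separately into each library stays open, although pancreas genes differed by a ratio of only 1.09 among the extract libraries and control 3 was at 0.893 of their mean, because similar amounts can arise by chance. No biological explanation was tested.

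The 3 against 3 libraries make 10 splits, too few for a share under 0.05: the real split, 1 of the 10, gave 4870 genes and the highest of the others 2. Over 18044 genes (99.9% of those tested), the log2 fold change had a Spearman rho of -0.105 with GC content and 0.151 with transcript length, where genes are not independent replicates. Reg3b was at 16.8 FPKM in extract 1 and between 0.154 and 0.991 FPKM in the other 5 libraries.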
